A study of Mus musculus with 4 samples.

How the data were processed

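The data are 4 circular chromosome conformation capture (4C-seq) libraries of mouse cells, 1 library per group. In 4C-seq, DNA contacts of 1 chosen fragment, the viewpoint, are read out by ligation, inverse PCR and sequencing. The labels name one viewpoint by the gene Il1a, measured in embryonic stem cells (ESC, line 46c) and in thioglycollate-elicited peritoneal macrophages given KLA for 1 h. They name the other by Tnfaip3, measured in ESC and in a library whose title says macrophage with KLA and whose source is the mouse macrophage-like line RAW 264.7. The treatment text of the labels speaks of KLA for peritoneal macrophages only, so no KLA time is given here for the RAW 264.7 library. Cells were fixed in 1% formaldehyde and digested with HindII and then DpnII, per the labels' protocols.

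Per the submitters' processing notes the build was mm9 and the tools were CASAVA 1.4 and Bowtie2 2.0.1; the notes used here give neither their role nor the program that made the smoothed profiles. The deposited values are a contact signal. Each deposited profile has 2001 positions, 1000 bp apart, with 145 columns that name no gene, chromosome or viewpoint. From the missing entries at the profile ends, the columns after the position were read as 48 window widths from 2 to 49 kb with 3 columns each, a central signal and an upper and a lower bound. The central signal reaches exactly 1 in each profile, so the deposited values were relative to the highest window of their own library. In at least 99.98% of the windows tested, the central value and its bounds obeyed a geometric mean with 1 constant offset per library, to a tolerance of 1e-06. The offset was 0.0359 for Il1a in ESC, 0.478 for Il1a in macrophages, 0.0129 for Tnfaip3 in ESC and 0.0180 for Tnfaip3 in RAW 264.7 cells, in units of the highest window. The central value was therefore read as a mean on a log scale, and the bounds as a spread among fragment ends inside a window, which is not an error between libraries. Windows at exactly 0 fell at the same positions in both libraries of a viewpoint (133 of the 2 kb windows at Il1a and 148 at Tnfaip3) and were treated as holding no fragment end. Read depth is unknown, so no counting interval was computed.

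Choices made before the data were examined were the main window of 10 kb, the distance range of 10 to 500 kb from the viewpoint, values as deposited with no pseudocount, and a threshold of 2-fold. The files give no viewpoint position, so whether the viewpoint was at the promoter of the named gene or at a distal element stays unknown here. The rule for this case took the middle of the highest 2 kb signal averaged over both libraries, here called the apex. A decreasing isotonic fit of log2 contact on distance, both sides pooled, gave the contact expected at each distance. The profile correlation was taken across positions on log2 contact minus this expectation. The distance slope was the least-squares slope of log2 contact on log2 distance. Lengths with at least 2-fold higher contact were counted at positions where the higher library was at or above its own expectation. Intervals were taken from 1000 resamplings of 50 kb blocks of positions, and of 20 kb blocks for the near-minus-far differences in the closing section. They describe variation along 1 pair of profiles, since positions are not replicates, and no p-value was computed.

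Regions were named by a rule written beforehand. It took, in each library, up to 5 local maxima at least 2-fold over expectation and 20 kb apart, and in each comparison the 5 longest runs of positions at least 2-fold higher in either cell type. The rule also asked for 3 fixed gene lists at their promoters and up to 15 further genes. That part was not run, because the annotation used here is RefSeq for GRCm38.p6, another build than mm9. It served only for gene order and chromosome, and no region was called an enhancer or a promoter. Runs that differ near the apex were added after the data were seen. For these, the log2 ratio was reduced by its median over windows 200 to 900 kb away, and runs of at least 5 positions within 100 kb of the apex were kept where the ratio lay outside the central 95% of those far windows.

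Alternatives covered window width, distance range, scaling between libraries, a pseudocount, the expectation, the filter on low contact and the thresholds. The middle of the profile as reference point, values in units of the offset, and median scaling with a 1.5-fold threshold were added after the data were seen. The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, scikit-learn 1.9.0 and Matplotlib 3.10.9. Then 2 simulated libraries with 3 regions raised 4-fold were compared over 982 positions. Away from the region edges, 100% of the changed positions and 0 positions outside these regions were called, and both offsets were recovered. Both simulated libraries had the same offset before scaling. They were compared after median scaling, without the filter on low contact and with a known viewpoint in the middle. The simulation therefore did not test values as deposited, unequal offsets or the choice of viewpoint position. The simulated libraries also shared most of their fragment noise, and 4-fold lies well above the 2-fold threshold. Differences as small and short as the runs near the apex, and the rule that found those runs, were not simulated.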

Results

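Contact profiles of 2 viewpoints were examined in ESC and in macrophage-type cells, with 1 library in each of the 4 groups. The stated purpose of the series was to look for physical contact between macrophage enhancers already marked in ESC and their promoters. Il1a encodes the inflammatory cytokine interleukin 1 alpha, and Tnfaip3 encodes A20, an inhibitor of NF-κB signalling. In the RefSeq annotation of GRCm38.p6, Il1a lies on chromosome 2 between Ckap2l and Il1b, and Tnfaip3 lies on chromosome 10 between Perp and Olig3. Positions are given in mm9 coordinates, as in the deposited profiles, which name no chromosome. The labels name each viewpoint by a gene, and its distance from that gene or its promoter is not given in the sources used here. Distances are therefore distances from the apex, the highest 2 kb window averaged over both libraries, not from the gene, and the viewpoint can be a distal element. The apex lay 8 kb from the middle of the profile at Il1a and 29 kb from it at Tnfaip3. The middle of the profile may be the viewpoint instead, at 129153157 for Il1a and at 19207921 for Tnfaip3. Each profile extends equally far to both sides of this point, as a grid built around the viewpoint would. At Tnfaip3 the apex was the highest 2 kb window in the macrophage-type library but not in ESC, where 19124921 had 1 against 0.987. If the middle is the viewpoint, the Tnfaip3 distances are measured from a point 29 kb away from it. The range of 10 to 500 kb then includes the viewpoint itself at Tnfaip3. The Il1a profiles ran from 128153157 to 130153157 and the Tnfaip3 profiles from 18207921 to 20207921. There were no replicates and read depth is unknown, so every difference compares 2 libraries and has no replicate error. Both macrophage-type libraries were labelled with KLA and none was without it, so cell type and KLA treatment cannot be told apart. A difference between the cell types below can come from either.

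For the Il1a viewpoint, contact was higher around the apex at 129161157 than far away in both ESC and KLA-treated peritoneal macrophages. Within 10 kb of the apex, the median contact was 2.17 times the level found 500 to 900 kb away in ESC and 2.59 times that level in macrophages. The apex was chosen as the highest signal, which raises these values; within 10 kb of the middle of the profile, a position not chosen by its contact, they were 2.03 times in ESC and 2.43 times in macrophages. At 10 to 25 kb it was 1.28 times the far level in ESC and 1.52 times in macrophages, and at 100 to 200 kb it was 1.07 and 1.05 times. Between 10 and 500 kb the slope of log2 contact on log2 distance was -0.055 in ESC (95% interval -0.099 to 0.012) and -0.077 in macrophages (95% interval -0.121 to -0.013). The side of higher coordinates held 50.4% of the contact in ESC (95% interval 45.7 to 54.3) and 49.9% in macrophages (95% interval 45 to 53.9).

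The Il1a profiles of the 2 cell types had much of their shape in common, which can reflect the layout of fragment ends as well as contacts (closing section). Without the distance expectation, the Spearman coefficient was 0.720 at 10 to 100 kb from the apex and 0.966 at 600 to 970 kb. Across 980 positions, contact relative to the distance expectation correlated between ESC and macrophages with a Spearman coefficient of 0.826 (95% interval 0.748 to 0.90) and a Pearson coefficient of 0.871 (95% interval 0.822 to 0.921). In both libraries the highest 2 kb windows were those centred at 129161157 and 129162157. In 10 kb windows no position 10 to 500 kb from the apex reached 2-fold over the distance expectation in either library, and in 5 kb windows 2 local maxima did so in ESC and 0 in macrophages. With a threshold of 1.5-fold and 10 kb windows, 5 local maxima were found in ESC and 2 in macrophages. The highest was at 128790157 in ESC, with 1.73 times expectation against 1.35 times in macrophages, and at 129148157 in macrophages, with 1.86 times expectation against 1.69 times in ESC.

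As deposited, the macrophage library had higher Il1a contact than ESC over 402 kb, counted at 2-fold or more, and ESC was higher over 0 kb. The median log2 ratio of macrophages over ESC was 1.11 (95% interval 1.08 to 1.15). The longest runs lay at 128912157 to 128946157, with a mean log2 ratio of 1.07, at 129348157 to 129370157, with 1.09, and at 129328157 to 129346157, with 1.33. Runs at 129539157 to 129555157 and at 129627157 to 129641157 had mean log2 ratios of 1.07 and 1.13. The median log2 ratio 200 to 900 kb away was 1.13, so only the run at 129328157 stood clearly above the library-wide difference. The higher contact in macrophages depended on scaling. Dividing each library by its median left 0 kb higher in either cell type. In units of the offset the count became 0 kb higher in macrophages and 515 kb higher in ESC. The highest window stood 9.42 times over the median 10 kb window in ESC and 4.34 times in macrophages.

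Relative to windows 200 to 900 kb away, Il1a contact in macrophages was higher in 2 stretches on the lower side of the apex and lower in 2 stretches on the other side. Contact was 1.28-fold higher in macrophages at 129149157 to 129154157, a run that holds the middle of the profile at 129153157, with a log2 ratio of 0.36 after subtraction of the far median. It was 1.41-fold higher at 129130157 to 129139157, with a log2 ratio of 0.50. At 129170157 to 129175157 and at 129245157 to 129252157 the log2 ratios were -0.34 and -0.37. The central 95% of far windows spanned log2 ratios from -0.25 to 0.25, a band that fixes in advance the share of far positions outside it. These 4 runs were found among 199 positions, and the far windows held 6 runs of at least 5 positions among 1402 positions. The regions were chosen after their values were seen, and none of the 4 lay outside the far windows in windows of 5, 20 and 49 kb alike. In these windows in that order the log2 ratio was 0.11, 0.11 and 0.23 at 129149157, -0.049, -0.0020 and 0.18 at 129130157, -0.71, 0.035 and 0.11 at 129170157, and -0.42, -0.20 and -0.049 at 129245157. The spreads within 10 kb windows overlapped between the cell types at 100% of positions 10 to 500 kb away, as deposited and after median scaling. As deposited, even the library-wide difference left them overlapping, so the overlap does not bear on differences as small as these runs.

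For the Tnfaip3 viewpoint, contact near the apex at 19236921 was higher than far away in both ESC and RAW 264.7 cells, by less than 2-fold. Within 10 kb of the apex the median contact was 1.55 times the level 500 to 900 kb away in ESC and 1.48 times in RAW 264.7 cells, and within 10 kb of the middle of the profile it was 1.73 and 1.51 times. At 10 to 25 kb from the apex it was 1.53 times in ESC and 1.80 times in RAW 264.7 cells. At 25 to 50 kb it was 1.5 times in ESC and 1.35 times in RAW 264.7 cells, and at 100 to 200 kb it was 1.02 and 1.07 times. The distance slope was -0.130 in ESC (95% interval -0.171 to -0.063) and -0.134 in RAW 264.7 cells (95% interval -0.185 to -0.051). With distances from the middle of the profile, the slopes were -0.106 in ESC and -0.110 in RAW 264.7 cells. The side of higher coordinates held 51% of the contact in ESC (95% interval 47.6 to 55.6) and 52% in RAW 264.7 cells (95% interval 48.3 to 56.8).

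**Figure D1:**
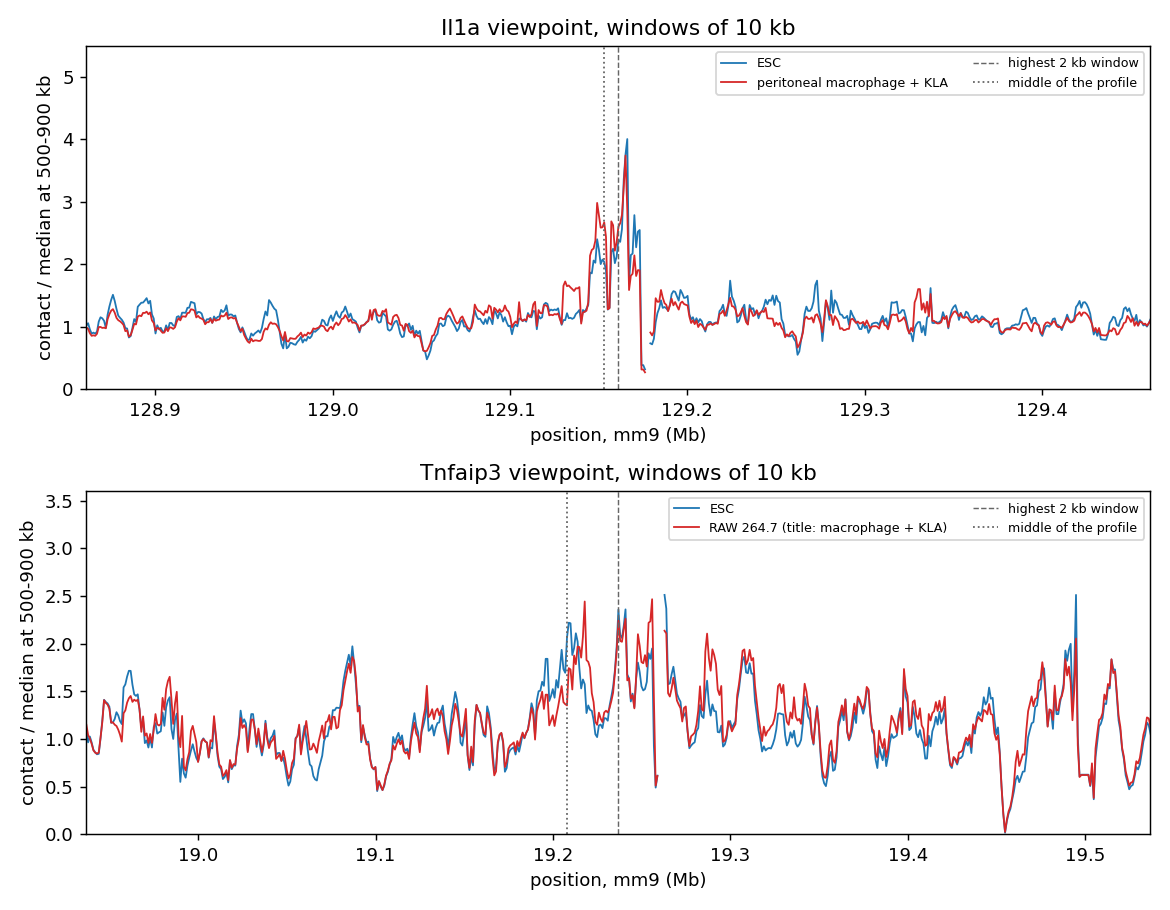
Contact in 10 kb windows, divided by the median of windows 500 to 900 kb from the apex, against mm9 position within 300 kb of the apex, for Il1a (top) and Tnfaip3 (bottom). Solid lines are single libraries, dashed lines mark the highest 2 kb window averaged over both libraries, dotted lines mark the middle of the profile, and gaps are windows with no fragment end. Median contact within 10 kb of the apex is 2.17 and 2.59 times the far level at Il1a and 1.55 and 1.48 times at Tnfaip3, in ESC and in the macrophage-type cells in that order.

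The Tnfaip3 profiles of ESC and RAW 264.7 cells were close to each other at the same scale, and here too the layout of fragment ends can contribute. Without the distance expectation, the Spearman coefficient was 0.858 at 10 to 100 kb from the apex and 0.904 at 600 to 970 kb. Across 979 positions the Spearman correlation of contact relative to expectation was 0.926 (95% interval 0.893 to 0.949) and the Pearson correlation 0.956 (95% interval 0.926 to 0.973). As deposited, the median log2 ratio of RAW 264.7 cells over ESC was 0.01 (95% interval -0.01 to 0.03). No position was 2-fold higher in either library, so the length was 0 kb in both directions. The ratio depended on scaling: in units of the offset its median was -0.47, with 1 kb higher in ESC. Contact at 19626921, 390 kb from the apex, was 2.05 times expectation in ESC and 2.35 times in RAW 264.7 cells. At 19494921 it was 2.60 times in ESC and 2.02 times in RAW 264.7 cells, and at 19734921 it was 2.13 times in ESC and 1.87 times in RAW 264.7 cells. The windows of 5 kb at 19494921 and 19734921 held no fragment end. In windows of 5 kb the local maxima at 2-fold reached the limit of 5 in both libraries, and in windows of 20 kb there were 0.

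Relative to far windows, contact in RAW 264.7 cells was lower than in ESC in 2 stretches 26 and 35 kb below the Tnfaip3 apex and higher in 1 stretch 51 kb above it. At 19204921 to 19210921 the log2 ratio after subtraction of the far median was -0.40, with a mean contact of 0.268 in ESC and 0.202 in RAW 264.7 cells. This run holds the middle of the profile at 19207921. At 19195921 to 19201921 the log2 ratio was -0.35. At 19287921 to 19294921 contact was 1.36-fold higher in RAW 264.7 cells, with a log2 ratio of 0.45. The central 95% of far windows spanned -0.30 to 0.37, which again fixes the share of far positions outside it. The 3 runs among 198 positions compare with 5 runs of at least 5 positions among 1402 far positions. These runs too were chosen after their values were seen, and none of the 3 lay outside the far windows in windows of 5, 20 and 49 kb alike. In these windows in that order the log2 ratio was -0.63, -0.26 and -0.16 at 19204921, -0.25, -0.33 and -0.15 at 19195921, and 0.56, 0.23 and 0.10 at 19287921. The spreads within windows overlapped at 100% of positions 10 to 500 kb away, as deposited and after median scaling. The typical spread among fragment ends, on signal plus offset, was 5.34-fold in ESC and 4.00-fold in RAW 264.7 cells. The overlap therefore does not bear on differences as small as these runs.

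**Figure D2:**
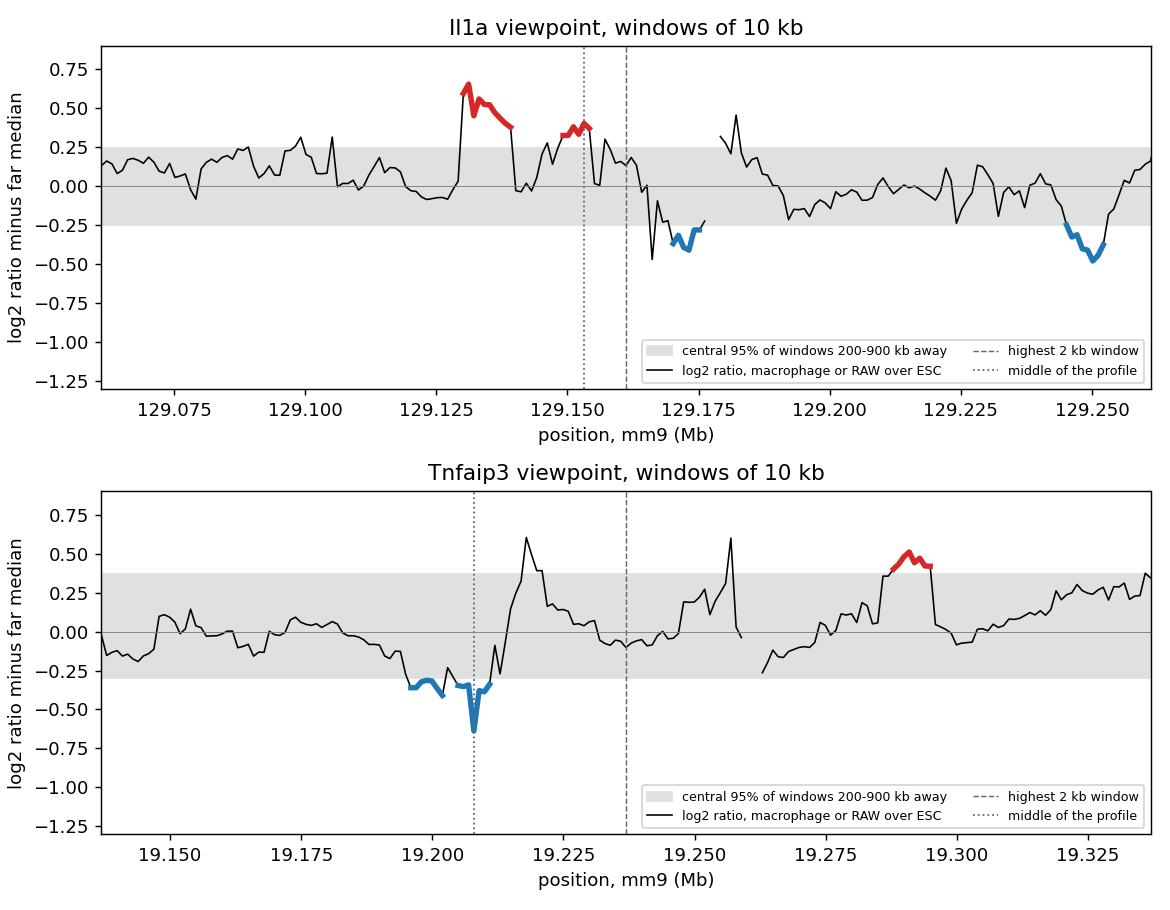
Log2 ratio of the macrophage-type library over ESC in 10 kb windows, minus its median 200 to 900 kb away, against mm9 position within 100 kb of the apex, for Il1a (top) and Tnfaip3 (bottom). The grey band is the central 95% of far windows, and thick red and blue lines are the 4 runs at Il1a and the 3 at Tnfaip3 that lay above or below it over at least 5 positions, each from 1 pair of libraries.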

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

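Values in units of the offset, distances from the middle of the profile, median scaling with a 1.5-fold threshold, recurrence at least 50 kb away and all alternatives for the runs near the apex were chosen after seeing the data; the other alternatives named here were planned. Read depth is unknown and each group had 1 library, so the alternatives show dependence on processing only. For the Il1a comparison 98 alternative values stayed within the main interval, or within 1.5 times of the main length, 17 left it and 1 reversed. For Tnfaip3 15 left it and 0 reversed. Of 42 alternative values for counts of local maxima and for runs near the apex at Il1a 6 moved and 4 reversed, and of 38 at Tnfaip3 18 moved. Scaling cannot move correlations, slopes or side shares. The cause was not tested for the values that follow, except where the range or threshold itself changes what is counted.

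For Il1a, windows of 5 kb gave a Spearman correlation of 0.930 and a Pearson correlation of 0.926. Positions up to 200 kb gave 0.658 and 0.812, a macrophage slope of -0.127 and 170 kb at least 2-fold higher in macrophages. That length was 897 kb over all positions, 779 kb with no filter on low contact and 12 kb at 3-fold. It was 0 kb with each library divided by its sum, 0 kb with division by its median and 5 kb with median scaling and a 1.5-fold threshold. The median log2 ratio was 0.0064 after division by the sum, 0.013 after division by the median and 1.05 with a pseudocount of 1%. In units of the offset it reversed to -2.62, with 0 kb higher in macrophages and 515 kb higher in ESC. The local maxima at 2-fold numbered 0 in both libraries, and 2 in ESC in windows of 5 kb. The run at 129130157 went from 0.50 to -0.049 in windows of 5 kb and to -0.0020 in windows of 20 kb, with 0.18 in windows of 49 kb, and the run at 129170157 from -0.34 to 0.035 in windows of 20 kb and 0.11 in windows of 49 kb.

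For Tnfaip3, windows of 5 kb gave 2 kb at least 2-fold higher in RAW 264.7 cells and a median log2 ratio of -0.033; windows of 49 kb gave a median of 0.042. The Pearson correlation was 0.924 in windows of 20 kb and 0.908 in windows of 49 kb. Up to 200 kb the Spearman correlation was 0.881, the Pearson correlation 0.916 and the slopes -0.196 in ESC and -0.190 in RAW 264.7 cells. At 1.5-fold 2 kb were higher in RAW 264.7 cells and 1 kb in ESC, and with median scaling 1 kb in each. In units of the offset the median log2 ratio was -0.47 and 1 kb was higher in ESC. The local maxima at 2-fold numbered 3 in ESC and 2 in RAW 264.7 cells. They were 5 in both, the limit, in windows of 5 kb, 0 in both in windows of 20 or 49 kb and up to 200 kb, and 1 in RAW 264.7 cells with a pseudocount of 1%, an expectation per side or distance from the middle of the profile. In windows of 49 kb the run at 19204921 moved to -0.16, that at 19195921 to -0.15 and that at 19287921 to 0.10, inside the far windows. The fixed gene lists at promoters were not run.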

Other observations

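The highest 2 kb windows of a viewpoint were in part different in the 2 cell types. In macrophages the window at 129149157, 12 kb from the Il1a apex, had a contact of 0.964, close to the highest window of that library, and in ESC it had 0.293. Each value is relative to the highest window of its own library. In 10 kb windows 200 to 900 kb away the median log2 ratio of macrophages over ESC was already 1.13, so much of this difference is library-wide. The window opens the run that holds the middle of the profile at 129153157. At Tnfaip3 the highest window of the ESC library was at 19124921, with a contact of 1 against 0.671 in RAW 264.7 cells, and the window at 19290921 had 0.665 in RAW 264.7 cells and 0.194 in ESC. Beyond the distance range of the comparisons, 1 local maximum passed 2-fold over expectation, at 18539921 in the Tnfaip3 profile of RAW 264.7 cells, with 2.13 times expectation against 1.4 times in ESC.

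All tests below were chosen after the results were seen.

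The first pattern is the Il1a contact that was about 2-fold higher in macrophages along the whole profile as deposited. The median log2 ratio 10 to 100 kb away minus that 500 to 900 kb away was 0.018 (95% interval -0.049 to 0.104). Division of each library by its own highest window and more contact in macrophages at every distance both predict a ratio alike near and far, so the test cannot separate them. The log2 ratio of -2.62 in units of the offset would exclude more contact only if 1 offset were the same number of reads in both libraries. Each profile is relative to its own highest window, which stood 9.42 times over the median 10 kb window in ESC and 4.34 times in macrophages. The values therefore do not give absolute contact, and both explanations stay open. The offset was 0.338 times that median in ESC and 2.07 times in macrophages, and its effect on the ratio was not tested.

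The second pattern is the set of 7 runs near the apex, which the width of the window changed. In their own direction the Il1a runs at 129130157, 129149157, 129170157 and 129245157 passed the far windows at 17, 38, 11 and 15 of 48 window widths from 2 to 49 kb, and at 4, 11, 11 and 15 of the 19 widths up to 20 kb; the Tnfaip3 runs at 19195921, 19204921 and 19287921 passed at 37, 23 and 8 of 48, and at 13, 19 and 8 of 19. The run at 129170157 passed them in the other direction at 2 widths, and the other runs at 0. That run had no value at widths of 2 and 3 kb. The counts include the 10 kb width at which the runs were chosen, and neighbouring widths share much of their sequence. They therefore describe the dependence on width and are no separate support. The run at 129130157 passed only at 8 to 11 kb and at 37 to 49 kb, and windows that wide reach well beyond the run. The runs at 129149157 and 19204921 lay 0 kb from the middle of the profile, so ligation products of the bait fragment itself could account for both if the bait lies there, a position not given in the sources used here. Single fragment ends that enter or leave a window and a larger log offset in the macrophage library at Il1a were not tested and stay open. The same holds for a difference in contact that comes with cell type or with KLA, which these libraries cannot tell apart.

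The third pattern is the shape shared by both cell types, in which most 2 kb windows held a value that recurred exactly at least 10 kb away, 79.2% and 83.6% at Il1a and 75.5% and 78.1% at Tnfaip3, in ESC and in the macrophage-type library in that order. Of window pairs at least 50 kb apart with equal values in ESC, 78.7% at Il1a and 83.7% at Tnfaip3 were also equal in the other library, against 0.225% and 0.117% of the other pairs, which is consistent with fragment ends laid out alike in both libraries. Shared contacts that weaken with distance from the viewpoint predict a higher correlation near the apex. In 10 kb windows at Il1a the Spearman correlation of contact 10 to 100 kb away minus that 600 to 970 kb away was -0.246 (95% interval -0.487 to -0.092). It was -0.153 (95% interval -0.254 to -0.080) without the 4 runs and 5 kb on each side, so the prediction was not met there. The far correlation of 0.966 left little room for a higher near value. Differences between the cell types near the apex would also lower the near value, so the test cannot decide on shared contacts at Il1a. At Tnfaip3 the difference of -0.046 (95% interval -0.198 to 0.046) leaves them open. Recurring 2 kb windows decide nothing here, since their correlations were all close to 1, 0.987 near and 0.985 far at Il1a and 0.977 near and 0.989 far at Tnfaip3. In windows whose value recurred in neither library the correlation was 0.896 near and 0.979 far at Il1a and 0.922 near and 0.863 far at Tnfaip3, with 28 near windows each. The 2 libraries were thus also alike in 2 kb windows whose value did not recur. Such a value can still follow from the layout of fragment ends, so these windows do not separate layout from shared contacts.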
